A study of Homo sapiens with 12 samples.

How the data were processed

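The data are 12 RNA-seq libraries of cardiomyocytes derived from the ChiPSC22 induced pluripotent stem cell line, 3 in each of 4 groups named in the labels: PLXNA4 lentivirus, control lentivirus, PLXNA4 siRNA and scramble siRNA. Per the labels' protocols, spheroids were dissociated on day 17, non-cardiomyocytes were reduced by 4 days in lactate medium, cultures were enriched with beads on day 30, and plated cells were treated in medium without serum and harvested after 72 h. The labels name 2 different RNA extraction kits, and give the molecule as polyA RNA beside a library kit that removes ribosomal RNA, so the RNA selection is uncertain. Sequencing was on a NovaSeq, per the labels' protocols.

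The deposited table gives counts per Ensembl gene for each library, as whole numbers that were not normalized. Per the submitters' processing notes the genome build was GRCh38, and Salmon, limma, edgeR and DESeq2 were used, with no role or order given. If Salmon made the table, the counts are rounded gene-level estimates that divide reads between similar genes. The annotation release and the strand setting are not given in the sources used here. Of 60240 gene IDs 60045 matched a symbol, and the 195 others held at most 0.0988% of a library's counts. Coordinates come from GENCODE 29 on GRCh38. Total counts ran from 14362653 to 56022001 per library; the 2 shallow libraries limit the precision of weakly expressed genes. Correlations of log2 CPM within groups were 0.968 to 0.989, and the chi-square per degree of freedom between libraries of a group was 4.32 to 252, so no pair agreed within sampling noise.

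Groups, comparisons, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined, except where the text says otherwise. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes with low counts were removed with filterByExpr at a minimum count of 10, leaving 18633, libraries were scaled with TMM, and all 12 libraries entered 1 robust quasi-likelihood fit, so that the groups share an estimate of the spread. The quasi-likelihood F test compared PLXNA4 virus with control virus, PLXNA4 siRNA with scramble siRNA, the difference of those 2 effects, and control virus with scramble siRNA. All adjusted p-values of genes are edgeR's with Benjamini-Hochberg adjustment over the tested genes, at 0.05. CPM values use TMM-scaled library sizes, with a prior count of 2 on the log2 scale.

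The lists hold 509 genes, of which 480 were measured. They cover sarcomere, desmosome, ion channel, calcium handling, hypertrophic stress, plexin, matrix, metabolic, signalling, stress and cell cycle genes and markers of other cell types, atrial and ventricular identity. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated per list, adjusting over the 31 lists; fry was an alternative. The genes named are PLXNA4, then the 6 largest rises and 6 largest falls among genes with a gene symbol, past the threshold, with a mean log2 CPM of at least 1 and no overlap between groups. From each list the 2 members of smallest p are added, or 1 where fewer than 3 members passed, and from a list with none the most abundant member may be named; some of these are left out of the text, and genes named outside this rule are said to be so.

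Alternatives were DESeq2 size factors, no factor beyond the library total, no filter and a stricter filter, the Wald test of DESeq2 1.42.0, limma-voom, fits on only the libraries of the compared groups, a replicate block, a minimum log2 fold change of 1 and leaving out each library. Removal of mitochondrial genes before scaling, and a fit without PLXNA4 virus replicate 1 for the siRNA and control comparisons, were added after seeing the data. For siRNA seed matches, words of 7 bases were searched in the 3' untranslated regions of 11880 of the 12891 tested genes with a mean log2 CPM of at least 1 (92.2%), taking each gene's longest annotated region of at least 50 bases, over 16316 words present in at least 50 genes, against 100 shuffles of the fold changes. Word counts and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

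The methods were tested on simulated data with 200 changed genes. For PLXNA4 virus against control virus 32.5%, 65.5% and 87.5% of them were recovered at folds of 1.5, 2 and 4 (18260, 18280 and 18282 genes), and for PLXNA4 siRNA against scramble 31.5%, 62% and 85.5%. The difference of effects recovered 4%, 49.75% and 81.25% of 400 changed genes. Unchanged genes made up 0% to 9.49% of the calls, above the nominal share in places, and none was called between the unchanged controls. All 6 changed lists were recovered at folds of 1.5 and 2, with 0 to 3 other lists called. The simulated genes were drawn independently, with no correlation within a list. That run therefore does not measure how often real lists of correlated genes are called falsely. A word planted at a log2 effect of -0.1, -0.2 or -0.4 ranked first in 20 of 20 runs each. Only falls were planted, and only in more common words than the rising words AGACGTA, GACGTAA and TGACGTA reported below, carried by 236, 167 and 230 genes. The runs therefore do not measure recovery of words that rare.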

Results

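RNA sequencing measured gene expression in cardiomyocytes made from ChiPSC22, an established human induced pluripotent stem cell line. The cells received a lentivirus carrying PLXNA4, a control lentivirus, a small interfering RNA (siRNA) against PLXNA4, or a scramble siRNA, and were harvested 72 h later. PLXNA4 encodes plexin A4, a transmembrane receptor of semaphorin signalling. The series studies hearts at the end stage of arrhythmogenic right ventricular cardiomyopathy, where it names PLXNA4 as higher. These 4 groups of 3 libraries ask what more and less PLXNA4 do to cardiomyocyte expression. Library totals ran from 14362653 to 56022001 counts. PLXNA4 siRNA replicate 3 (14362653) and virus control replicate 2 (15156505) were the shallowest, and the other libraries held 37428924 counts or more. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

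Mitochondrially encoded genes took 18.4% of the counts in PLXNA4 virus replicate 1 but 6.04% and 6.86% in replicates 2 and 3. In the virus controls the share was 9.82% ± 0.297 (SD, n = 3). It was 7.38% ± 0.221 after PLXNA4 siRNA and 8.36% ± 0.286 after scramble siRNA (SD, n = 3 each). The 95% Wilson intervals of these single-library shares were at most 0.0304 percentage points wide and cover counting error only. On the first principal component, which held 38.9% of the variance, the PLXNA4 virus libraries lay at 64.1 to 97.5 and the other libraries at -33.5 to -19.1.

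PLXNA4 (ENSG00000221866.9; GRCh38 chromosome 7, 132123332 to 132648688, minus strand, protein coding) moved as the labels describe in each library. In CPM (counts scaled to a common library size) it stood at 224, 202 and 225 in virus control replicates 1 to 3 and at 734, 1147 and 937 in the PLXNA4 virus replicates. In the siRNA experiment it stood at 243, 258 and 244 after scramble siRNA and at 20.8, 19.3 and 17.9 after PLXNA4 siRNA. The virus raised it 4.33-fold (log2 fold change 2.11, SE 0.130, edgeR adjusted p = 1.85e-07), and the siRNA lowered it 12.8-fold (log2 fold change -3.68, SE 0.142, edgeR adjusted p = 3.78e-08). Between the virus and scramble controls its log2 difference of -0.19 did not pass (edgeR adjusted p = 0.407). The plot of PLXNA4 and mitochondrial share shows each library.

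**Figure D1:**
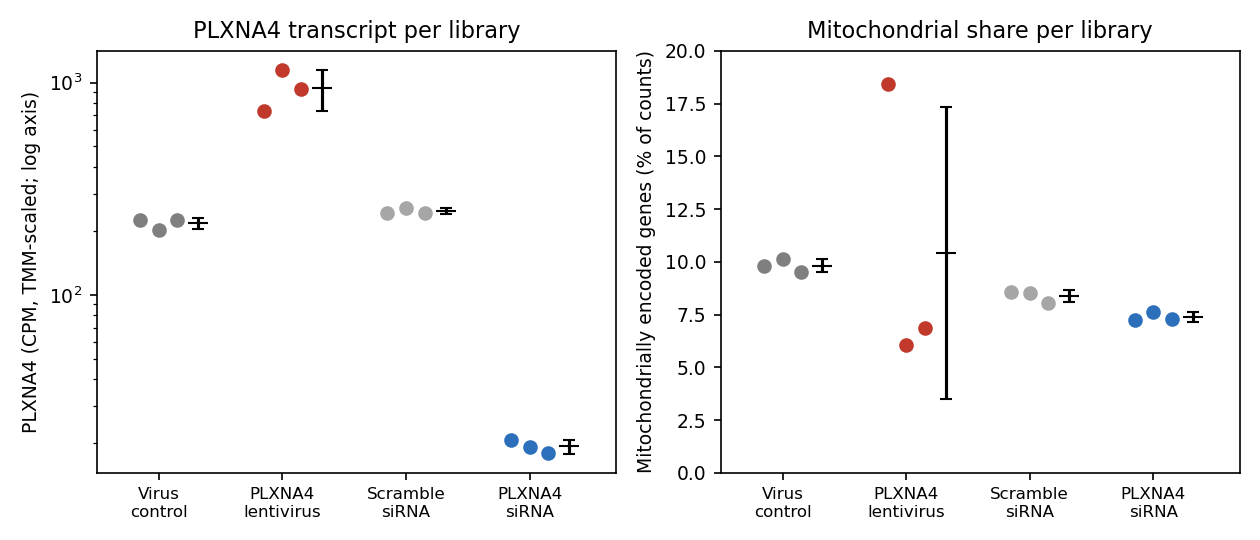
PLXNA4 in CPM on a log axis and the percent of counts in mitochondrially encoded genes, 1 point per library, with a black bar at the mean ± SD (n = 3) of each group. PLXNA4 averages 939 CPM with its virus against 217 in virus controls and 19.3 CPM with its siRNA against 248 after scramble siRNA, while PLXNA4 virus replicate 1 stands at a mitochondrial share of 18.4%.

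Cells given the PLXNA4 virus had lower cell cycle, ventricular, sarcomere and ion channel transcripts and higher hypertrophic stress and immediate early transcripts than cells given the control virus. All 24 measured cell cycle genes fell, with a median log2 fold change of -1.55, among them TYMS, the thymidylate synthase of DNA precursor synthesis, at -1.84 and MCM4, a subunit of the replicative helicase, at -1.08. All 8 ventricular markers fell as well, at a median of -0.87, including the transcription factor gene HEY2 at -1.57 and the gap junction gene GJA1 at -1.08. Of the 12 natriuretic peptide and hypertrophic stress genes 9 rose and 1 fell, with a median of 1.03. NPPA, the atrial natriuretic peptide, went from 71.9 ± 8.25 to 193 ± 16.9 CPM, and ANKRD1, a stress-responsive ankyrin repeat protein of cardiac muscle, from 265 ± 11.0 to 1188 ± 195 CPM (SD, n = 3 each).

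In total 7480 of 18633 tested genes passed an edgeR adjusted p of 0.05, 3698 higher and 3782 lower with the PLXNA4 virus, and 2233 of them changed by at least 1 on the log2 scale. The groups' libraries did not overlap for 47.6% of tested genes, against a chance share of 10%. The count was 8274 without PLXNA4 virus replicate 1, the library of high mitochondrial share, and 6653 without the shallow virus control replicate 2. It was 5732 and 5754 without virus control replicates 1 and 3, and 4999 when the spread was estimated from these 6 libraries alone. The long noncoding RNA NEAT1 (ENSG00000245532.9; chromosome 11, 65422774 to 65445540), the scaffold of nuclear paraspeckles, rose 30.7-fold, from 15.9 ± 1.75 to 485 ± 80.8 CPM (SD, n = 3 each, edgeR adjusted p = 6.59e-09). The stress-induced transcription factor ATF3 (chromosome 1, 212565334 to 212620777) rose from 1.36 ± 0.260 to 29.5 ± 8.06 CPM (SD, n = 3 each, edgeR adjusted p = 6.27e-08). Other large rises were LUCAT1 at a log2 fold change of 5.07, the histone gene H4C5 at 4.52, the microtubule-associated protein gene MAP2 (chromosome 2, 209424058 to 209734118) at 3.84 and the small MAF factor gene MAFF at 3.67. LUCAT1 is annotated as antisense and the strand of counting was not given, and H4C5 has near-identical histone copies, so both values are uncertain. PTGDS (chromosome 9, 136975092 to 136981742), a prostaglandin D2 synthase, fell 19.9-fold, from 81.4 ± 6.29 to 4.10 ± 0.196 CPM (SD, n = 3 each, edgeR adjusted p = 8.55e-10). GJA5, which encodes the gap junction protein connexin 40, fell 11.6-fold, from 65.5 ± 6.52 to 5.70 ± 1.54 CPM (SD, n = 3 each). The melanin synthesis gene DCT (chromosome 13, 94436808 to 94479682) had a log2 fold change of -4.69, the integrin gene ITGA10 of -3.98, CALN1 of -3.97 and the collagen gene COL11A2 of -3.80, all lower.

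Among 31 gene lists fixed in advance, 18 moved against the other genes in camera with a preset correlation, 8 upward and 10 downward. With an estimated correlation 7 held: ventricular markers (adjusted p = 0.00351), cell cycle (0.00933), sarcomere (0.0201), neural markers (0.0201), natriuretic peptide and hypertrophic stress (0.0206), immediate early (0.0206) and cardiac ion channels (0.0399). Adjusted over the list alone, 304 list members passed rather than 290 over all genes, and the counts were equal for 21 of the 31 lists.

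Sarcomere and myofilament genes fell as a group (camera adjusted p = 4.53e-12), with 17 of 24 lower, 2 higher and 5 not past the test (17 lower and 4 higher adjusted over the list alone). The M-band gene MYOM2 fell 3.32-fold and the atrial myosin light chain gene MYL7 fell 3.98-fold. Cardiac ion channels fell (camera adjusted p = 1.76e-05), with 9 of 18 lower and 2 higher (9 and 3 adjusted over the list alone), among them KCNIP2, a subunit of the transient outward potassium channel, 9.82-fold lower and the pacemaker channel gene HCN4 2.67-fold lower. Of 14 calcium handling genes 8 fell and 3 rose (camera adjusted p = 2.02e-04; adjusted p = 0.0621 with an estimated correlation); ATP2A2, the calcium pump of the sarcoplasmic reticulum, fell 2.00-fold and the phosphatase inhibitor gene PPP1R1A fell 3.20-fold. The ventricular and cell cycle lists had camera adjusted p = 1.09e-10 and 7.47e-41, and the hypertrophic stress list had 2.55e-06. Desmosome and intercalated disc genes were mixed, with 8 of 18 higher and 3 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.630), and CTNNA3, an alpha catenin of the intercalated disc, fell by 1.36 on the log2 scale. Of 9 atrial markers 3 rose and 2 fell (camera adjusted p = 0.571), with NPPA at 1.42 and MYL7 at -1.99.

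**Figure D2:**
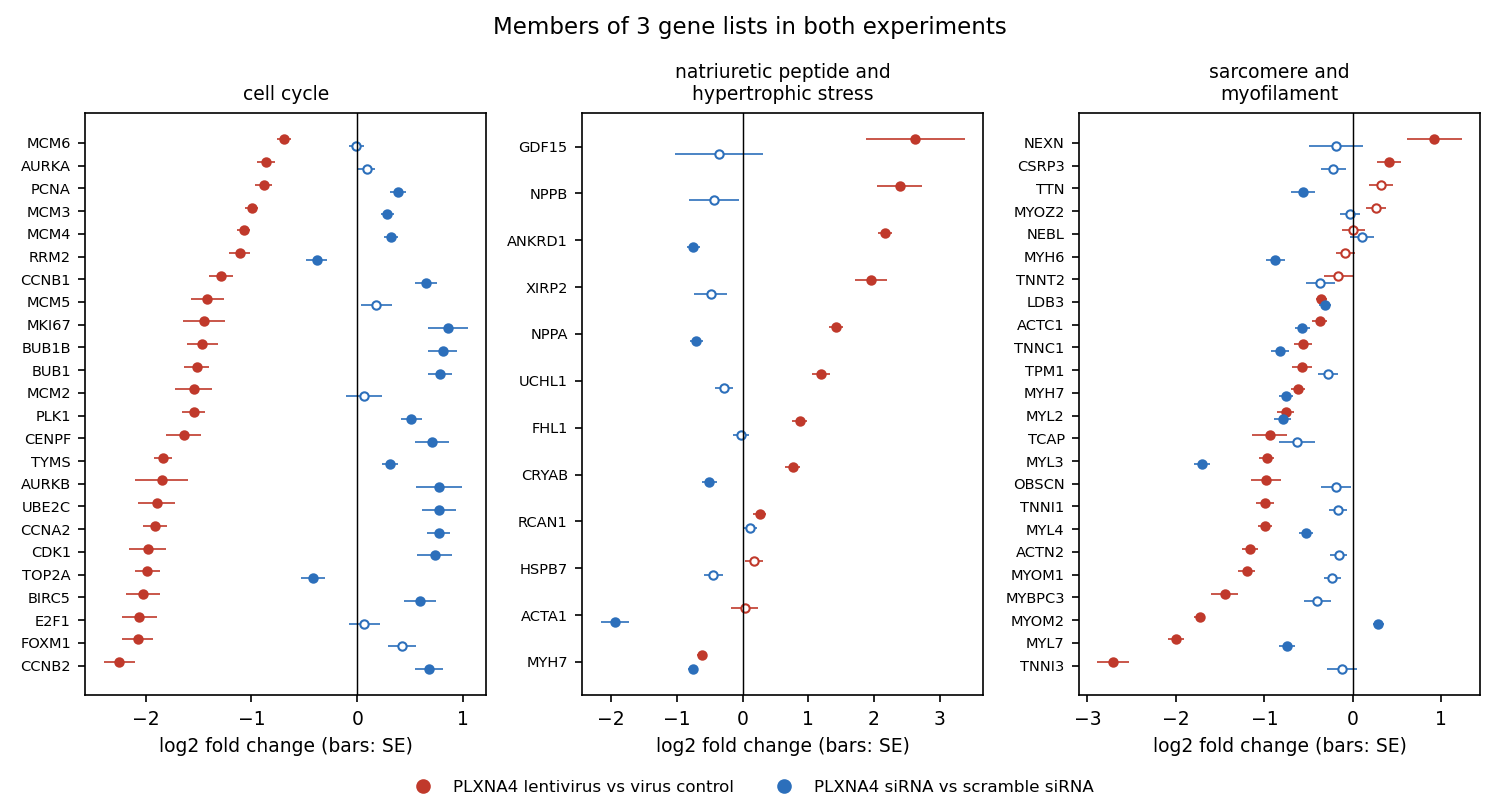
Log2 fold changes of the members of the cell cycle, natriuretic peptide and hypertrophic stress, and sarcomere lists with the PLXNA4 virus against its control (red) and with PLXNA4 siRNA against scramble siRNA (blue), with bars of 1 SE and filled points at an edgeR adjusted p under 0.05. With the virus all 24 cell cycle genes are filled and below 0, whereas with the siRNA 16 are filled above 0 and 2 below.

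Plexin, semaphorin and neuropilin genes other than the target were lower with the PLXNA4 virus, with 17 of 27 lower and 1 higher (18 and 1 adjusted over the list alone; camera adjusted p = 7.13e-06; adjusted p = 0.0813 with an estimated correlation). The plexin gene PLXNC1 fell 3.30-fold and the semaphorin gene SEMA6D fell 1.75-fold. Of 23 plexin signalling and cytoskeleton effector genes 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.0697). Members included DPYSL3, a collapsin response mediator, at 1.09 and the kinase gene PAK1 at 0.69. That list passed without PLXNA4 virus replicate 1 (adjusted p = 0.0129). Of 9 Wnt targets 6 fell, including the feedback gene AXIN2 at -1.19, and 2 rose (camera adjusted p = 0.00602; adjusted p = 0.0947 with an estimated correlation). YAP and TAZ targets moved upward with 4 of 12 higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.00820; adjusted p = 0.103 with an estimated correlation), a call lost with no low-count filter (adjusted p = 0.0519), and the matricellular gene CCN1 rose by 1.70.

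Immediate early and MAPK feedback genes rose, with 14 of 19 higher and 1 lower at a median of 1.23 (camera adjusted p = 1.89e-11). The ETS factor gene ETV5 rose by 2.47 and the MAPK inhibitor gene SPRY4 by 2.35. Of 25 interferon response genes 15 rose and none fell (18 and 1 adjusted over the list alone) at a median of 1.13, with IFIH1, a sensor of double-stranded RNA, at 1.54 and IFIT2 at 1.45. The interferon list passed with the preset correlation (camera adjusted p = 1.62e-05) and lost its call with the other (adjusted p = 0.279 with an estimated correlation). NF-kB and inflammatory genes showed 8 of 14 higher and 1 lower (camera adjusted p = 0.0212; adjusted p = 0.0929 with an estimated correlation), with the apoptosis inhibitor gene BIRC3 at 2.65 and the adhesion gene VCAM1 at -1.16. The list's adjusted p was 0.0532 without PLXNA4 virus replicate 3. Of 18 unfolded protein and integrated stress response genes 8 rose and 3 fell (camera adjusted p = 0.00221; adjusted p = 0.220 with an estimated correlation). HERPUD1, which acts in degradation of proteins of the endoplasmic reticulum, stood at 0.82. Of 18 p53 targets 11 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.194), with TP53INP1 at -1.18 and GADD45A at 0.93; the list passed without PLXNA4 virus replicate 1 (adjusted p = 0.0170).

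Among metabolic lists, glycolysis and hypoxia genes moved upward, with 8 of 18 higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.00171; adjusted p = 0.0813 with an estimated correlation). The glycolytic enzyme gene ENO1 rose by 1.78 and the pyruvate dehydrogenase kinase gene PDK1 fell by 1.36. Nuclear-encoded oxidative phosphorylation genes moved downward, with 11 of 22 lower and none higher at a median of -0.23 (camera adjusted p = 0.00804; adjusted p = 0.0813 with an estimated correlation). Among them were SDHA at -0.54 and UQCRC2 at -0.46. None of the 13 mitochondrially encoded genes passed (median 0.44, camera adjusted p = 0.660), and the most abundant, MT-CO1, stood at -0.43 (edgeR adjusted p = 0.285). Without PLXNA4 virus replicate 1 MT-CO1 stood at -1.09 (edgeR adjusted p = 2.98e-08) and the list was lower (adjusted p = 4.20e-05); nuclear copies of mitochondrial genes can share these reads. Of 18 fatty acid oxidation genes 5 fell and 2 rose (camera adjusted p = 0.361), with the fatty acid transporter gene CD36 at -1.74 and the kinase gene PDK4 at 2.54. Of 13 adipogenesis and lipid storage genes 4 fell and 2 rose, with a negative median of -0.10, a mean of -0.02 and an upward test that did not pass (camera adjusted p = 0.580). The desaturase gene SCD rose by 2.53 and the lipid droplet gene PLIN4 fell by 1.89. Cholesterol synthesis genes split evenly, 6 higher and 6 lower of 18, with a median of 0.11, a mean of -0.11 and a downward test that did not pass (camera adjusted p = 0.954), and the regulator gene SREBF2 stood at -1.13.

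Markers of other cell types moved apart. Of 10 smooth muscle and pericyte markers 6 fell and 1 rose (camera adjusted p = 0.00820; adjusted p = 0.279 with an estimated correlation). Members included the calponin gene CNN1 at -1.23 and SMTN at -1.13. Of 10 epicardial markers 4 fell and 1 rose (camera adjusted p = 0.0211; adjusted p = 0.0813 with an estimated correlation), with ITLN1 at -2.23 and UPK3B at -3.25. The epicardial call was lost without PLXNA4 virus replicate 2 (adjusted p = 0.0504) or replicate 3 (adjusted p = 0.0532). Of 7 neural markers 4 rose and 1 fell (camera adjusted p = 9.98e-05), with MAP2 at 3.84 and the growth cone gene GAP43 at 2.28. Of 11 fibroblast markers 4 fell and none rose (camera adjusted p = 0.0930), including S100A4 at -1.28 and MFAP4 at -0.79. Of 25 extracellular matrix and fibrosis genes 7 fell and 5 rose (camera adjusted p = 0.225). Examples were elastin, ELN, at -2.46 and TGFB2 at 0.94. Without PLXNA4 virus replicate 3 both lists passed (adjusted p = 1.23e-05 for fibroblast markers and 1.18e-11 for matrix genes). Of 11 endothelial markers 1 rose, the receptor gene KDR at 0.54, and 1 fell (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.660). Of 9 endoderm and hepatic markers 2 rose and 1 fell, the apolipoprotein gene APOA1 at -0.90, and the median of 0.50 and mean of 0.48 stood against a downward test that did not pass (camera adjusted p = 0.959). Of 3 pluripotency markers 1 fell, DNMT3B at -0.50 (edgeR adjusted p = 0.0214), with a median of 0.04, a mean of -0.06 and camera adjusted p = 0.836. Its call was lost without virus control replicate 1 (edgeR adjusted p = 0.0530), virus control replicate 3 (0.0573) or PLXNA4 virus replicate 2 (0.0665), with no low-count filter (0.0707) and with the compared libraries alone (0.0678).

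**Figure D3:**
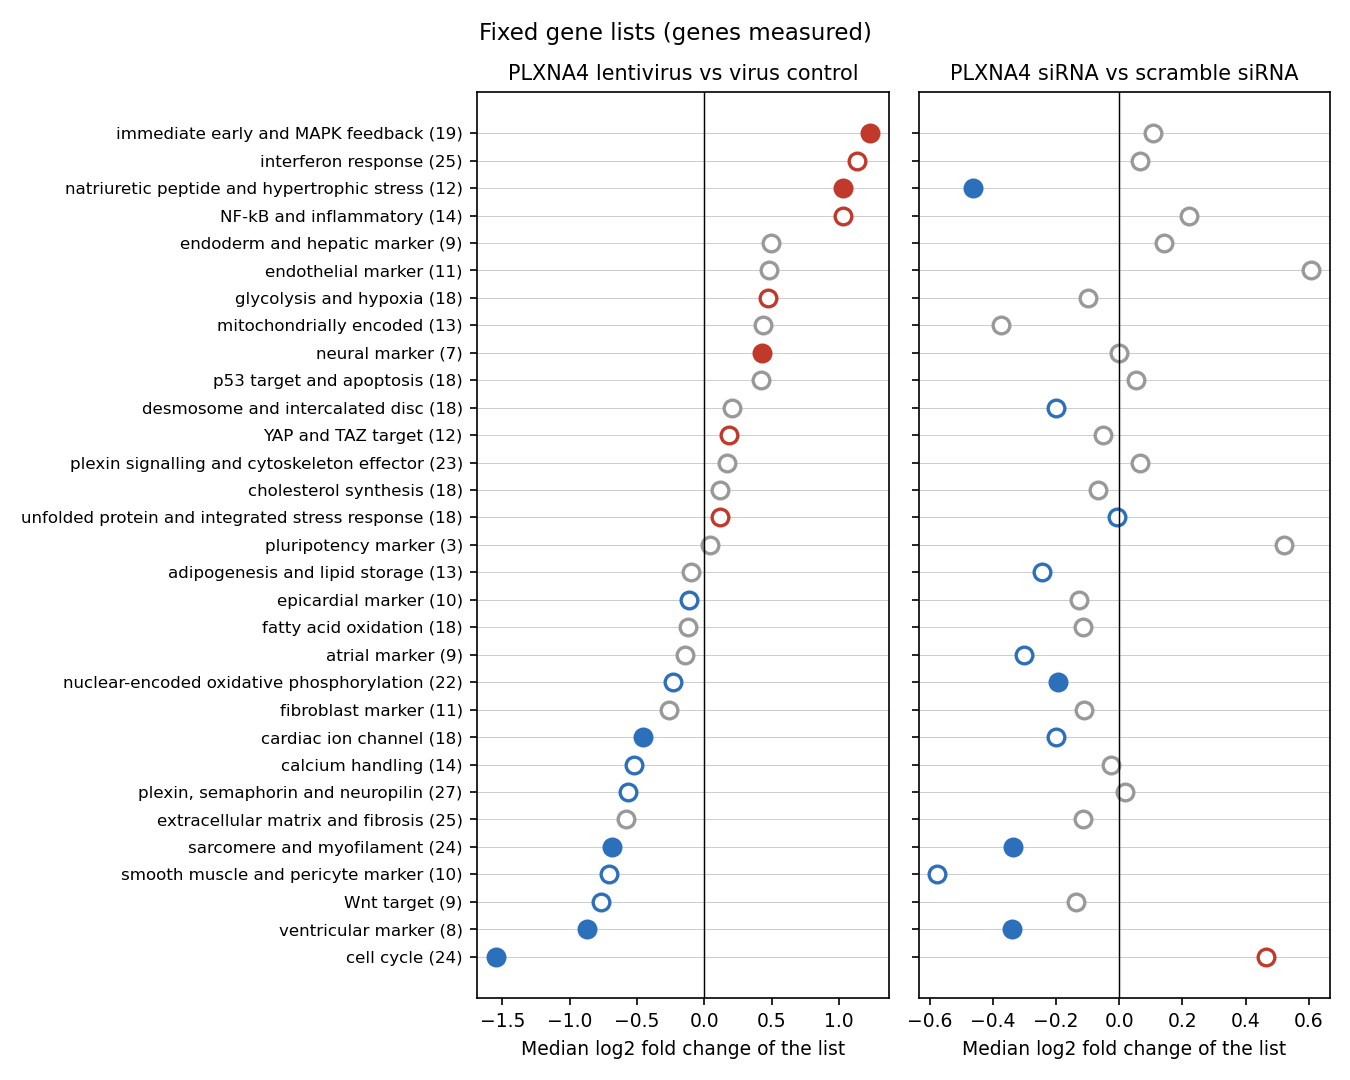
Median log2 fold change of each of the 31 gene lists with the PLXNA4 virus and with PLXNA4 siRNA, with the number of genes measured in parentheses; a coloured ring marks a list past an adjusted p of 0.05 in camera with a preset correlation, a filled point one that also passes with an estimated correlation, and grey one that did not pass. The virus moved 18 lists and the siRNA 11, of which 7 and 4 are filled.

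After PLXNA4 siRNA, sarcomere, ventricular, hypertrophic stress and oxidative phosphorylation transcripts were lower than after scramble siRNA. Of 24 sarcomere and myofilament genes 10 fell and 1 rose at a median of -0.34. MYL3, the ventricular essential myosin light chain (chromosome 3, 46857872 to 46882169), went from 2247 ± 10.3 to 691 ± 37.1 CPM and MYH7, the beta myosin heavy chain, from 23101 ± 867 to 13695 ± 899 CPM (SD, n = 3 each). Of 24 cell cycle genes 16 rose and 2 fell at a median of 0.47 (adjusted p = 0.175 with an estimated correlation), including the cyclin gene CCNA2 at 0.77 and the spindle checkpoint kinase gene BUB1 at 0.78.

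In total 1897 of 18633 genes passed, 1013 higher and 884 lower after PLXNA4 siRNA, of which 160 changed by at least 1 on the log2 scale. The groups' libraries did not overlap for 40.3% of tested genes, against a chance share of 10%. The largest fall after PLXNA4 itself was SETD7 (chromosome 4, 139495941 to 139606699), a lysine methyltransferase gene, from 121 ± 2.66 to 27.5 ± 1.20 CPM (SD, n = 3 each, edgeR adjusted p = 4.48e-09). The skeletal actin gene ACTA1 (chromosome 1, 229431245 to 229434098) fell 3.85-fold, ORC3 (chromosome 6, 87590067 to 87667453), a subunit of the origin recognition complex, 3.80-fold, and the nucleic acid binding protein gene YBX3 (chromosome 12, 10699089 to 10723312) 3.57-fold. VAT1 fell 3.52-fold and MYL3 fell 3.25-fold. Rises were smaller: the kinetochore gene CENPH by 1.43 on the log2 scale, CMAHP by 1.38, the receptor tyrosine kinase gene MET by 1.35, PODXL2 by 1.34, the cell cycle transcription factor gene E2F2 by 1.33 and the histone gene H3-3A by 1.31. CMAHP is a pseudogene and H3-3A has processed copies, and how reads were divided between ACTA1 and ACTC1 or MYH7 and MYH6 was not given in the sources used here, so these values are uncertain. The count was 1278 without the shallow PLXNA4 siRNA replicate 3, 1111 without replicate 1, 1049, 1083 and 1104 without scramble replicates 1, 2 and 3, and 4458 when the spread was estimated from these 6 libraries alone. With no factor beyond the library total the higher calls made up 75.2% of the calls rather than 53.4%, and in a fit without PLXNA4 virus replicate 1, chosen after seeing the data, 3907 genes passed.

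Of these genes ORC3, YBX3 and VAT1 carry 1 of 2 overlapping 7-base words in the 3' untranslated region that 39.2% of falling genes and 19.8% of the genes searched carry. CENPH, MET and H3-3A carry 1 of 3 other words found in 15.4% of rising genes and 4.28% of the genes searched. SETD7, ACTA1 and MYL3 among the falls and PODXL2 and E2F2 among the rises carry none of these words, and CMAHP was not searched. Of the other genes picked by the rule for the siRNA, VCL, NDUFA4, ZMAT3, ATP2A2, NDUFS1, SC5D, KDM3A and VCAM1 carry a word of the first kind. Of these KDM3A and VCAM1 were higher, at 0.28 and 0.29. Their calls were lost in several alternatives, such as KDM3A without scramble replicate 2 (edgeR adjusted p = 0.151) and VCAM1 without scramble replicate 1 (edgeR adjusted p = 0.124). The calls of ATP2A2, NDUFS1 and SC5D were also lost in some alternatives. SEMA6A, DPYSL3 and DNMT3B carry a word of the second kind. The words were chosen by a search of these same fold changes, so the shares are not independent of that choice.

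**Figure D4:**
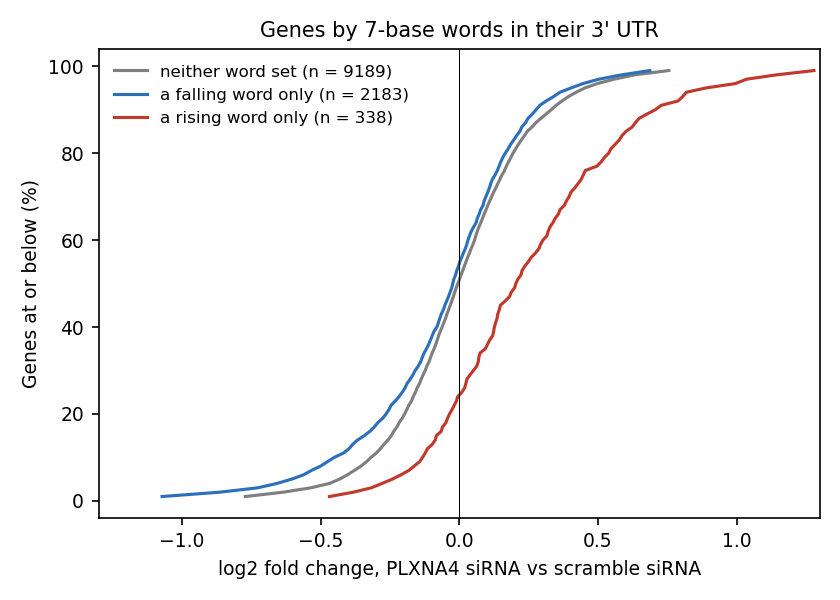
Percent of genes at or below each log2 fold change after PLXNA4 siRNA against scramble siRNA, with 1 line each for genes carrying neither set of words (n = 9189), only a falling word (n = 2183) and only a rising word (n = 338) in the 3' untranslated region; 170 genes with both are not drawn. The falling word line lies to the left of the line for genes with neither word at the low end, and the rising word line lies to the right.

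Of the 31 lists 11 moved in camera with a preset correlation, 2 upward and 9 downward. With an estimated correlation 4 held: sarcomere (adjusted p = 0.0132), ventricular markers (0.0132), natriuretic peptide and hypertrophic stress (0.0258) and nuclear-encoded oxidative phosphorylation (0.0264). Adjusted over the list alone, 124 list members passed rather than 99, and the counts were equal for 17 lists. Lists share genes such as MYH7, MYL3 and NPPA, so their tests are not independent.

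The sarcomere list (camera adjusted p = 3.93e-14) had 14 lower and 1 higher adjusted over the list alone. Of 8 ventricular markers 4 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 5.32e-07). Of 9 atrial markers 3 fell, including MYL7 at -0.75 and NPPA at -0.71 (camera adjusted p = 0.00232; adjusted p = 0.196 with an estimated correlation). Natriuretic peptide and hypertrophic stress genes fell, 5 of 12 with none higher (6 adjusted over the list alone; camera adjusted p = 1.48e-07). Nuclear-encoded oxidative phosphorylation genes fell, 4 of 22 with none higher (9 adjusted over the list alone; camera adjusted p = 1.57e-05). NDUFA4, a respiratory chain subunit gene, stood at -0.58, and the mitochondrially encoded share of counts was 7.38% against 8.36%. The 13 mitochondrially encoded genes did not pass (median -0.38, camera adjusted p = 0.264), with MT-CO1 at -0.33. They passed as lower with the spread from the compared libraries alone (adjusted p = 1.86e-07; MT-CO1 edgeR adjusted p = 0.00140) and in the fit without PLXNA4 virus replicate 1 (2.04e-07; MT-CO1 0.00206). Desmosome genes showed 4 of 18 lower and 2 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0130; adjusted p = 0.0679 with an estimated correlation), with XIRP1 at -0.76 and vinculin, VCL, at -0.42. This call was lost with no factor beyond the library total (adjusted p = 0.0735). Of 18 cardiac ion channels 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0351; adjusted p = 0.304 with an estimated correlation). Members included the T-type calcium channel gene CACNA1G at -1.34 and the inward rectifier gene KCNJ2 at 0.95. The channel call was lost with the stricter filter (adjusted p = 0.0785) and without scramble replicate 1 (adjusted p = 0.0564) or PLXNA4 siRNA replicate 3 (0.0746). Of 14 calcium handling genes 3 fell and 2 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.908), with calsequestrin, CASQ2, at 0.53.

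Cell cycle genes moved upward as a list with the preset correlation (camera adjusted p = 8.82e-10; adjusted p = 0.175 with an estimated correlation), with 17 higher and 2 lower adjusted over the list alone. Unfolded protein and integrated stress response genes had 4 of 18 higher and none lower (5 adjusted over the list alone), a median of -0.01, a mean of 0.11 and an upward test (camera adjusted p = 0.0376; adjusted p = 0.505 with an estimated correlation). Examples were the disulfide isomerase gene PDIA4 at 0.91 and SEL1L, a part of the degradation machinery of the endoplasmic reticulum, at 0.58. That call was lost with the stricter filter (adjusted p = 0.0674) and without scramble replicate 1 (adjusted p = 0.103) or PLXNA4 siRNA replicate 3 (0.0542). Of 10 smooth muscle and pericyte markers 7 fell and none rose (8 adjusted over the list alone; camera adjusted p = 3.05e-09; adjusted p = 0.0534 with an estimated correlation). Among them were the actin regulator gene LMOD1 at -0.90 and the kinase gene MYLK at -0.84. Of 13 adipogenesis and lipid storage genes 2 fell, including the lipase gene LPL at -0.86 (camera adjusted p = 0.0233; adjusted p = 0.505 with an estimated correlation), a call lost without PLXNA4 siRNA replicate 3 (0.0542).

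The other lists did not pass after PLXNA4 siRNA in camera with a preset correlation. Of 27 plexin, semaphorin and neuropilin genes 1 rose, SEMA6A at 0.43 (camera adjusted p = 0.622), and of 23 plexin signalling genes 1 rose, DPYSL3 at 0.73 (camera adjusted p = 0.210). YAP and TAZ targets had 4 of 12 lower and 2 higher (5 and 3 adjusted over the list alone; camera adjusted p = 0.243), with ANKRD1 at -0.75 and AMOTL1 at 0.47. Of 25 matrix genes CCN2 alone fell, at -0.58 (camera adjusted p = 0.243). Of 25 interferon genes IFIT1 alone fell, at -0.54 (median 0.06, mean 0.09, downward test, camera adjusted p = 0.908), and of 10 epicardial markers LRRN4 alone fell, at -0.71 (camera adjusted p = 0.227). Immediate early genes had 1 of 19 higher, SPRY2 at 0.54, and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.479). Fatty acid oxidation genes had 2 of 18 lower, with FABP3 at -0.70 (camera adjusted p = 0.191, but 0.0330 with no low-count filter and 0.0380 in the fit without PLXNA4 virus replicate 1), and cholesterol synthesis genes 3 of 18 lower (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.371). Glycolysis and hypoxia genes had 1 of 18 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.458), Wnt targets 1 of 9 lower (camera adjusted p = 0.458) and NF-kB genes 1 of 14 higher (camera adjusted p = 0.458). Endothelial markers had KDR higher at 0.72 (camera adjusted p = 0.147, but 0.0330 with no low-count filter and 0.0179 without PLXNA4 siRNA replicate 2), neural markers had nestin, NES, lower at -0.57 (camera adjusted p = 0.458), and pluripotency markers had DNMT3B higher at 1.03 (camera adjusted p = 0.243). No fibroblast marker (camera adjusted p = 0.591), endoderm marker (0.891) or p53 target (0.891) passed; MFAP4 stood at -0.11, AFP at 0.26 and ZMAT3 at 0.00, and AFP passed with the compared libraries alone (edgeR adjusted p = 0.0120).

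Whether more and less PLXNA4 had opposite effects was asked by comparing both experiments. Across the 18633 tested genes the log2 fold changes correlated near 0 (Pearson r = 0.00279, Spearman rho = 0.0142), where genes are not independent replicates. Over the 1897 siRNA calls r was -0.151 (rho -0.124) and over the 1191 genes called in both -0.164 (rho -0.163), sets selected by the calls themselves. The 1191 genes past the threshold in both made up 62.8% of the siRNA calls, of which 662 (55.6%) moved in opposite directions and 529 in the same. Genes lower with the virus and higher with the siRNA numbered 422 against 206 for independent lists, and genes lower in both 292 against 179. Genes higher with the virus and lower with the siRNA numbered 240 against 175, and genes higher in both 237 against 201. MYL7 fell in both experiments, while ANKRD1 and NPPA rose with the virus and fell with the siRNA. The count in both was 2453 without PLXNA4 virus replicate 1, 667, 689 and 696 without scramble replicates 1, 2 and 3, and 697 without PLXNA4 siRNA replicate 1. In the test of the difference between the 2 effects 5122 genes passed, 2370 with a higher and 2752 with a lower effect of the virus.

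The control groups were compared as the background of both experiments. Virus control cells had lower immediate early and YAP and TAZ target transcripts and a lower alpha myosin heavy chain than scramble siRNA cells. Of 19 immediate early genes 10 were lower and none higher (11 lower adjusted over the list alone; camera adjusted p = 5.77e-17; adjusted p = 0.0279 with an estimated correlation). FOS was at 0.582 ± 0.0465 against 12.0 ± 0.959 CPM and EGR1 at 9.63 ± 0.890 against 70.4 ± 2.28 CPM (SD, n = 3 each). MYH6, the alpha myosin heavy chain gene, which shares sequence with MYH7, was at 426 ± 21.0 against 2221 ± 66.6 CPM (SD, n = 3 each). YAP and TAZ targets were lower (4 of 12, with 1 higher; 5 and 1 adjusted over the list alone; camera adjusted p = 9.93e-06; adjusted p = 0.0386 with an estimated correlation), including CCN1 at -1.57 and CCN2 at -1.39. Nuclear-encoded oxidative phosphorylation genes were higher (5 of 22, none lower; 11 adjusted over the list alone; camera adjusted p = 3.72e-05; adjusted p = 0.0386 with an estimated correlation). Of 11 endothelial markers 4 were lower and none higher (6 lower adjusted over the list alone; camera adjusted p = 2.64e-04; adjusted p = 0.0579 with an estimated correlation), with PECAM1 at 0.457 ± 0.126 against 3.29 ± 1.11 CPM (SD, n = 3 each). Calsequestrin, CASQ2, was higher by 1.06 and the chaperone gene HSPA5 by 0.83. Matrix (camera adjusted p = 2.64e-04), smooth muscle (0.00148), epicardial (0.0118) and fibroblast lists (0.0457) were lower too. None of these held with an estimated correlation (adjusted p = 0.0973 to 0.600). In all 14 lists passed with a preset correlation, 4 higher and 10 lower, and 3 held with an estimated one. The genes named for this comparison were chosen after their values were seen.

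Cells given the control virus differed from cells given scramble siRNA in 1516 genes, 899 higher and 617 lower, of which 250 changed by at least 1 on the log2 scale. Delivery agent, any batch and the scramble sequence cannot be told apart here, and this comparison shares the scramble libraries with that of PLXNA4 siRNA. The groups' libraries did not overlap for 42.3% of tested genes, against a chance share of 10%. The count was 826, 894 and 748 without virus control replicates 1, 2 and 3, 628, 743 and 772 without scramble replicates 1, 2 and 3, and 5008 when the spread was estimated from these 6 libraries alone. With no factor beyond the library total 71.6% of calls were higher rather than 59.3%, and without PLXNA4 virus replicate 1 in the fit, an alternative chosen after seeing the data, 3571 genes passed.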

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

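The comparison of cell cycle genes with markers of other cell types, the removal of mitochondrial genes and the random lists before the length and GC trend was removed were tests chosen only after the result was seen. The effects of the PLXNA4 virus and of PLXNA4 siRNA, each against its own control, differed in 5122 genes by edgeR's test of the difference itself. Of 100 splits drawn from the 200 ways to regroup both experiments, 2 gave as many, the real one included, and the highest of the others gave 5469. That highest split kept both experiments' groups whole and exchanged the labels of 1 of them, so it counts the sum of the 2 effects and not their difference. The 11 drawn splits that kept the virus groups whole and mixed the siRNA groups gave 2650 to 3188 genes, and the 87 that mixed the virus groups, and so put the virus effect into the spread, gave 0 to 115. Of the 31 lists 12 differed in camera, each given as its median difference of log2 fold changes, virus minus siRNA. The medians were -2.13 for cell cycle, 1.73 for natriuretic peptide and hypertrophic stress and 0.99 for neural markers, which held with an estimated correlation (adjusted p = 0.00793, 0.00793 and 0.0307). They were 1.25 for immediate early genes, 1.16 for interferon response, 0.32 for glycolysis and hypoxia and 0.32 for YAP and TAZ targets. They were -0.0703 for sarcomere, -0.24 for cardiac ion channels, -0.45 for calcium handling, -0.60 for plexins and semaphorins and -0.65 for ventricular markers. For these 9 lists the adjusted p = 0.0636 to 0.377 with an estimated correlation. For the PLXNA4 virus alone, the 10 splits of the 6 libraries are too few for a share under 0.05: the real split, 1 of the 10, gave 7480 genes and 18 lists, and the highest others gave 0 genes and 14 lists.

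One pattern weighed is the movement of 18 lists with the PLXNA4 virus, where 1 library had a mitochondrial share of 18.4%. All 18 lists kept their direction and call without that library, which argues against it as the whole cause; 18 also kept them with mitochondrial genes removed, but this moved the median of all genes by only -0.0035 and decides nothing on the mitochondrial share. A trend on transcript length and GC content, which held 3.36% of the variance, was removed. After that, 16 medians kept their side with a one-sided random-list p under 0.05, against 10000 lists of random genes of like expression. Within this selection their p ran from 0.0001, the smallest it can be, to 0.0272. That side was the one camera gave on these same fold changes, and genes were drawn as if independent. The test thus asks only whether the trend removes a call and adds no support for it. YAP and TAZ targets (0.104) and neural markers (0.0975) had not passed this test before the removal. The unfolded protein list went from a median of 0.11 (permutation p = 0.140) to -0.02 (0.421) and the epicardial list from -0.11 (permutation p = 0.309) to -0.10 (0.329), neither past this test before or after, so the trend stays open for these lists. What also stays open, untested, is whether PLXNA4 itself or the load and response to this virus moved the lists, since there was 1 PLXNA4 construct and 1 control virus, and the interferon genes may belong to either.

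The fall of all 24 cell cycle genes with the PLXNA4 virus could come from fewer cells of other, cycling types, although lactate medium and bead selection are meant to remove them. If markers and cell cycle transcripts came only from such cells, their loss as a whole would lower both about as far. The cell cycle median was -1.55, and the lowest of 4 marker lists, smooth muscle, had a median of -0.71 (SE of its mean 0.222). The fibroblast, epicardial and endothelial lists had -0.26, -0.11 and 0.48, the last mostly of genes near the floor. Among abundant markers, MFAP4 stood at 213 ± 37.7 against 368 ± 47.7 CPM, ACTA2 at 504 ± 109 against 441 ± 8.63 and TAGLN at 352 ± 58.6 against 179 ± 22.2 (SD, n = 3 each), all of which cardiomyocyte cultures can express, and DCN varied widely between PLXNA4 virus libraries (41.7 ± 39.0 CPM) where TYMS did not (13.9 ± 1.03 CPM). An earlier form of this test, met if any marker list lay above 0 by more than its SE, was met by the endothelial list (0.48, SE 0.398) and was replaced because 1 list can move alone. ACTA2 and TAGLN were the only 2 of 10 smooth muscle members above 0, and 6 lay below -0.5. Of 11 fibroblast members 5 lay below -0.5 and 4 above 0. The epicardial list had a mean of -0.62 (SE 0.441), with 4 of 10 members below -0.5 and 3 above 0. The fibroblast list had a mean of -0.49 (SE 0.220) and passed as lower without PLXNA4 virus replicate 3 (camera adjusted p = 1.23e-05), so it depends on that library. Because cardiomyocyte cultures can express markers such as ACTA2 and TAGLN, smaller marker falls do not decide on a loss of other cells as a whole. That loss stays open, as do loss of a single cycling type and reduced cycling of the cardiomyocytes, which was not tested apart.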

How the results depend on the processing

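The removal of mitochondrial genes, and the fit without PLXNA4 virus replicate 1 for the siRNA and control comparisons, were chosen after seeing the data. For the PLXNA4 virus 63 of 66 named genes kept direction and side of the threshold under every alternative run for genes, and for PLXNA4 siRNA 42 of 51. The exceptions were 3 and 9; none turned direction. Under the other scalings, filters, library sets, block and left-out libraries 23 and 24 of 31 lists kept theirs, which leaves out the estimated correlation and fry. Without a low-count filter the virus lists of plexin signalling (adjusted p = 0.0389), matrix (0.0221), p53 targets (0.0289) and fibroblast markers (0.0118) passed, as did the siRNA lists of fatty acid oxidation and endothelial markers (0.0330 each). The PLXNA4 virus count stayed within 4999 to 8274 and the difference of effects within 3827 to 6854 across alternatives other than the fold minimum. A minimum log2 fold change of 1 left 2233 genes for the virus, 160 for the siRNA, 1978 for the difference, 250 between controls and 43 in both, by its construction. Estimating the spread from the compared libraries alone gave 4458 genes for the siRNA, 5008 between controls and 4999 for the virus. The fit without PLXNA4 virus replicate 1 gave 3907 for the siRNA and 3571 between controls. The PLXNA4 virus libraries stood furthest apart, at a chi-square per degree of freedom of 27.1 to 252 against 4.32 to 12.2 within the other groups. They enter the spread that all groups share in the main fit, so the virus and siRNA counts are not a like measure of the 2 effects. Other causes of these shifts were not tested. Of the 1897 siRNA calls 1893 were shared in direction with the first of these fits and 1895 with the second. Leaving out 1 library gave 1049 to 1404 genes for the siRNA, 628 to 894 between controls and 667 to 2453 in both; fewer libraries leave fewer degrees of freedom, but the rise to 2453 without PLXNA4 virus replicate 1 was not tested for its cause. Lists past the threshold fell to 7 for the virus and 4 for the siRNA with an estimated correlation; the cause was not tested. The correlation of the 2 effects was -0.0174 with the stricter filter and -0.0410 to 0.0258 leaving out 1 library; the cause was not tested. The mitochondrially encoded list turned lower with the virus without PLXNA4 virus replicate 1 (adjusted p = 4.20e-05), the library with the 18.4% share, within a range of 4.20e-05 to 0.695 over the left-out libraries. In the siRNA comparison it passed as lower with the compared libraries alone (adjusted p = 1.86e-07) and without PLXNA4 virus replicate 1 (2.04e-07), and stayed at 0.0735 to 0.417 under the others. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0984 to 0.0353, and 4 of 12 libraries correlated best with their own number. With a replicate block 1020 genes passed for the siRNA, 605 in both and 6050 for the virus. The virus list of fibroblast markers then passed as lower (camera adjusted p = 0.0317). Between controls 56 genes passed with the block, a count that does not compare with the 1516. The block lay within each experiment, so that test compared only the fitted levels of replicate 1. Scaling moved the median of all genes by at most 0.0781. Totals of 14362653 and 15156505 counts in 2 libraries limit weakly expressed genes.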

Other observations

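The dose comparison, the sets of genes carrying a word and the tests by whether a list holds carriers were tests chosen only after the result was seen. Genes that fell after PLXNA4 siRNA often carried a short word in the 3' untranslated region. Among 16316 words of 7 bases TAACCAA was most tied to falls (z = -15.7, against -4.77 as the lowest of any word in 100 shuffles), followed by the overlapping TTAACCA (z = -15.3), and TAACCAA had z = 0.17 with the PLXNA4 virus. One or both were carried by 323 of 825 falling genes (39.2%) and by 19.8% of genes searched, including ORC3, YBX3, VAT1 and VCL, whereas SETD7, ACTA1, MYL3 and MYH7 carried neither. Of carriers 13.7% fell, against 5.27% of other genes. Both words occur in the PLXNA4 transcript ENST00000359827.7, TTAACCA in the coding sequence of exon 3 (chromosome 7, 132489465 to 132489471) and TAACCAA in the 3' untranslated region of exon 32 (132128272 to 132128278), although 47.6% of all such words occur somewhere in its 13786 bases. Genes that rose were tied to AGACGTA (z = 9.69, against 4.59 as the highest in shuffles), GACGTAA (9.45) and TGACGTA (9.02). Those 3 words were carried by 139 of 902 rising genes (15.4%) and 4.28% of genes searched, including CENPH, MET and H3-3A. AGACGTA had z = 10.5 between virus control and scramble siRNA, a comparison that shares the scramble libraries, and z = -0.16 with the PLXNA4 virus.

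A candidate explanation for these gene sets is seed pairing, in which an siRNA lowers transcripts that match its seed: of the PLXNA4 siRNA for TAACCAA (z = -15.7), and of the scramble siRNA in the control for AGACGTA (z = 9.69), but neither siRNA sequence was given in the sources used here. Only the 2 falling and 3 rising words above were counted as carried. Others past the shuffles, such as AACCAAA (z = -8.86) and GACAGTA (z = 7.99, in 22.1% of rising genes), were not, so pairing through them stays open for every list. Without word carriers 9 of 11 lists kept direction and call, but 6 of these held no carrier, so removal tested nothing there. In 4 of them (sarcomere, smooth muscle, ventricular and unfolded protein) 0 of 59 members searched carried a counted word, where genes shared by lists are counted in each. This argues against direct pairing of the counted words in those lists. With an estimated correlation, smooth muscle and unfolded protein had camera adjusted p = 0.0534 and 0.505. Of the 5 lists with carriers 3 kept the call. Hypertrophic stress, with 1 carrier, stayed at a mean of -0.55 (camera adjusted p = 1.57e-07). Oxidative phosphorylation, with 3 carriers, went from -0.22 to -0.21 (6.23e-04). Cell cycle, a call made with the preset correlation (adjusted p = 0.175 with an estimated correlation), went from a mean of 0.41 to 0.51 (9.24e-14). Its 3 carriers had a mean of -0.27, so their removal could only raise this list. The 21 members left held the rise without a counted word. In these 3 lists the values argue against direct pairing of the counted words as the whole cause. In contrast, desmosome went from a mean of -0.19 (SE 0.0790) to -0.19 (SE 0.123, adjusted p = 0.138) and cardiac ion channels from -0.26 (SE 0.105) to -0.26 (SE 0.118, adjusted p = 0.0783), where fewer members widened the error; with an estimated correlation they had adjusted p = 0.0679 and 0.304 before removal. Seed words stay open for these 2, and for the atrial and adipogenesis lists, where 77.8% and 69.2% of members were searched; the dose of PLXNA4 stays open too, because 55.6% of the genes called in both experiments moved in opposite directions, which decides nothing when the virus also changed many other genes, and the labels name 1 PLXNA4 siRNA product, so PLXNA4 loss and other effects of that product cannot be told apart for single genes.

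For PLXNA4 siRNA the 10 splits of the 6 libraries are too few for a share under 0.05: the real split, 1 of 10, gave 1897 genes and 11 lists, and the highest others gave 0 and 8. Between the control groups, the 10 splits of the 6 control libraries are too few for a share under 0.05: the real split, 1 of 10, gave 1516 genes and the highest other gave 1.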
